A study of Homo sapiens with 2 samples.

How the data were processed

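RNA was measured in 2 samples of PC3, a human prostate cancer cell line that lacks functional p53 and grows without androgen. One culture stably overexpressed a control microRNA and the other stably overexpressed miR-95, a small RNA that represses messenger RNAs with sequences complementary to its seed. Per the labels' protocols, both lines were grown in serum-containing medium, total RNA was purified on columns, and biotin-labelled target was hybridised to an Affymetrix gene array. Each group holds 1 array.

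The deposited table gives log2 expression values for 23641 probe sets on both arrays, rounded to 2 decimals. The scale was read from the values, which ran from 1.94 to 13.84 on the control array and from 1.79 to 13.83 on the miR-95 array. Affymetrix Expression Console 1.2 was used, per the submitters' processing notes. The summarisation method, background correction, between-array scaling, genome build and any filter are not given in the sources used here. The sorted values of the 2 columns differed by at most 0.04 between the 1st and the 99th percentile, as arrays forced towards a common distribution do. Because such scaling sets the overall level of the arrays equal, a shift of all transcripts together would not show.

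Platform annotation gave 1 gene symbol to 14088 probe sets (59.6%) and several to 0. The other 9553 probe sets carry no gene name here and entered no gene comparison. All 14088 Entrez identifiers matched the RefSeq table of assembly GRCh38.p14, which was used only for names, gene span and gene order. This gave 13864 genes, of which 167 had more than 1 probe set. The log2 values of a gene's probe sets were averaged. Each array was then centred on its median over genes (7.46 control, 7.495 miR-95), which lowered the miR-95 values by 0.035 relative to the control. All differences are miR-95 minus control on the log2 scale.

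A gene counted as detected when its higher value was at or above the median of that array, which kept 7081 genes. Detected genes were counted as different at 1.5-fold and at 2-fold. With 1 array per group there is no test of the difference between conditions, no standard error and no p-value, and every statement describes these 2 arrays. A guide to measurement disagreement came from the 68 detected genes with several probe sets, where the differences given by the most distant probe sets corresponded to a spread of 0.126. It holds no variation between cultures. The number of arrays limits the precision of every value.

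Before the data were examined, 45 gene lists were fixed. For each of the 33 lists with at least 5 detected members, the median difference was placed as a percentile among 10000 random lists of the same size drawn from detected genes in the same 20 bins of mean expression. Random lists whose median tied with that of the list were split equally between the sides. Percentiles below 2.5 or above 97.5 are called outside the central range. At the nominal rate about 1.7 of 33 lists would lie outside by chance. Of 200 simulated lists without a shift 8.0% did so, too few lists to show whether the true rate exceeds the nominal one. Co-regulated members would add to the rate, because genes are not independent replicates. The genes named were also set by rule: the 12 detected genes with the largest difference each way (ties at the last place included), leaving out Y-linked genes and symbols that start with a fixed set of prefixes (among them LOC, RNU, SNOR, MIR and LINC) or are open reading frame or clone names, plus SGPP1, SNX1 and the 2 detected members of each list with the largest difference each way, or more past 1.5-fold. Fewer members than the rule allows are named, mostly in lists inside the central range. Named outside the rule, after their values were seen, are CCNE1, MCM10, MKI67, TIPIN, DDX60, DUSP6, LIF, ICAM1, TIGAR, SPHK1, SGPL1, UGCG, PTGS2, CCL2, CXCL6, RNF43, AXIN2, LUM and CHGB. The rule left out 2 symbols among the higher genes and 0 among the lower ones. No probe set used here named the miR-95 gene, and none named a member of the integrin, proteasome or replication-dependent histone lists. A planned search for miR-95 seed sites was not run because no 3′ untranslated sequences were used here.

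The steps were tested on simulated data drawn from the mean expression of these genes with a spread of 0.148. Over 20 simulations with about 7056 detected genes, 99.8% of genes raised by 1 log2 unit and 99.5% of genes lowered by 1 passed 1.5-fold, against 10.6% and 11.6% of those changed by 0.4 each way and 0.007% of unchanged genes. The simulated noise was normal and of the same size at every brightness, with its spread taken from these same arrays. It held no variation between cultures, so the 0.007% is not a rate of false calls in the real data. Of 200 random lists of 20 genes without a shift, 8.0% lay outside the central range, and 91.0% of 100 lists shifted by 0.15 lay above it. The alternatives were loess (span 0.4), quantile or no centring, an offset of 32 before log2, the brightest probe set per gene, no filter or filters at the 25th or 75th percentile, and unmatched random lists. Matching on gene span as well was added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.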

Results

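Gene expression was compared between 2 stable derivatives of PC3 prostate cancer cells, one overexpressing a control microRNA and the other miR-95, to find which transcripts differ when miR-95 is raised. Each group was measured on 1 array, so no value below has a replicate error or a test. The rise of miR-95 itself could not be checked, since no probe set used here named it. Pairs of array values are given as deposited, before centring, while folds and differences are after centring, which lowered the miR-95 values by 0.035 relative to the control. The arrays were close to each other, with a Pearson correlation of 0.9959 across all 23641 probe sets. Of the 7081 detected genes 59.4% had a negative difference, the share against which sign counts of the lists below are to be read. Over these genes the median difference was -0.035, the same size as the centring shift, so the excess of negative signs depends on the centring. Their robust SD was 0.148. That SD was 0.163 in the 2362 dimmest detected genes and 0.133 in the 2357 brightest. Differences declined with the genomic span of the gene (Spearman's rho = -0.238 across the 7081 genes, which are not independent replicates). The median difference was 0.015 in the 1771 shortest genes and -0.075 in the 1770 longest.

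SGPP1, the phosphatase that removes the phosphate of sphingosine-1-phosphate (S1P), was 1.68-fold lower on the miR-95 array after centring (10.08 against 10.79 as deposited). It ranked 18th from the lowest of the 7081 detected genes. SNX1, a sorting nexin of the endosomal retromer, was 1.17-fold lower after centring (9.72 against 9.91 as deposited) and ranked 784th. Both had been listed as reported targets of miR-95 before the data were examined. Whether SGPP1 was first picked from these arrays is not given in the sources used here, so its value is not counted as independent evidence. The difference of SGPP1 is several times the 0.126 spread between probe sets of one gene, and that of SNX1 is within about 2 such spreads. Each gene was read by 1 probe set.

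Of 47 genes of sphingolipid metabolism and S1P signalling, 32 were measured and 23 detected. Of these, 2 were at least 1.5-fold lower on the miR-95 array and 1 was at least 1.5-fold higher, while the other 20 passed neither limit. The lower genes were SGPP1 and SGMS2, a sphingomyelin synthase, which was 1.74-fold lower. The higher gene was S1PR2, a receptor for S1P, which was 1.54-fold higher after centring (9.46 against 8.80 as deposited). PLPP3, a lipid phosphate phosphatase, and ORMDL2, a regulator of serine palmitoyltransferase, were each 1.27-fold higher, and UGCG, the glucosylceramide synthase, differed by -0.265 on the log2 scale. SPHK1, the kinase that makes S1P, and SGPL1, the lyase that cleaves it, differed by 0.005 and -0.055. The list median was -0.01, at the 77.68th percentile of matched random lists, so the list did not stand apart as a whole.

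**Figure D1:**
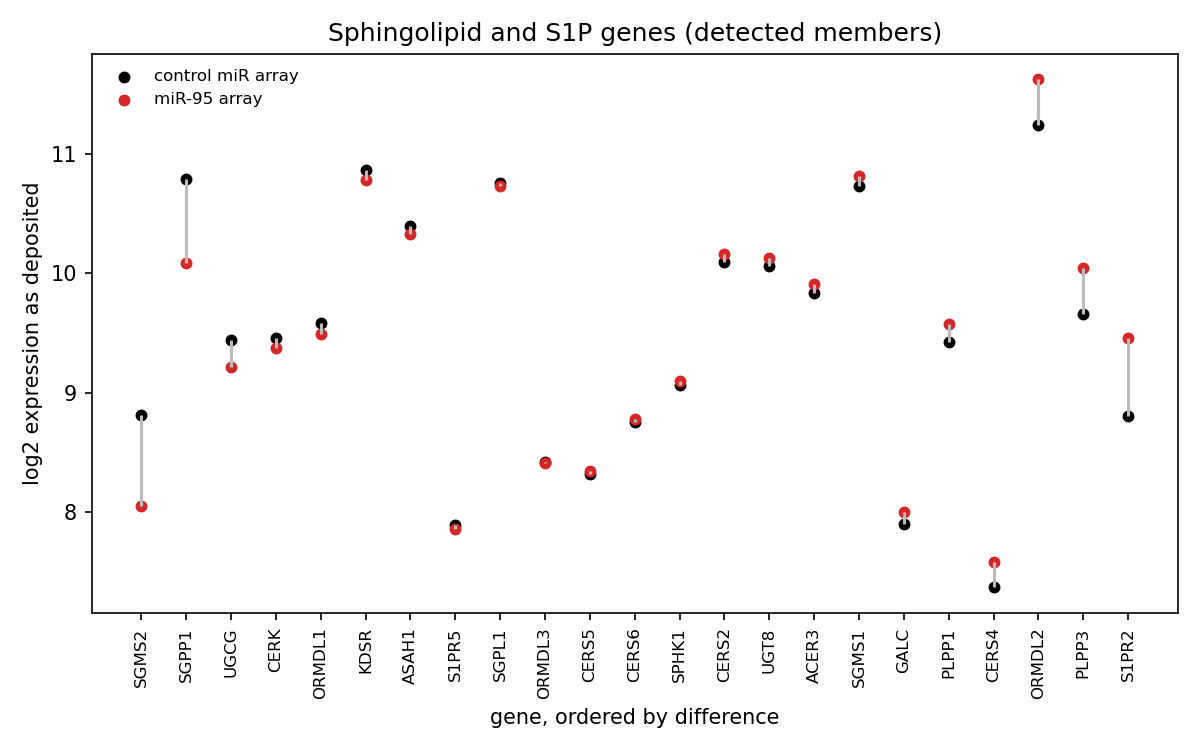
Log2 expression as deposited (vertical axis) of the 23 detected sphingolipid and S1P genes on the control array (black) and the miR-95 array (red), 1 array each, ordered by difference; grey lines join the 2 values. The widest gaps are SGMS2 (8.05 against 8.81) and SGPP1 (10.08 against 10.79), lower on the miR-95 array, and S1PR2 (9.46 against 8.80), higher.

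Across all detected genes, 28 were at least 1.5-fold higher and 61 at least 1.5-fold lower on the miR-95 array, together 1.26% of those detected. Only 1, GALNT1, passed 2-fold upwards, and 0 passed it downwards. The excess of lower genes depended on the centring. It was 68.5% of the 89 genes with median centring, 54.9% with the values as deposited (37 higher, 45 lower), 58.0% after loess and 57.5% after quantile normalization.

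The genes with the largest higher values included GALNT1, an enzyme that starts mucin-type O-glycosylation, at 2.05-fold after centring (11.42 against 10.35 as deposited). TP53INP1, a stress-induced protein that acts with p53 family members, was 1.87-fold higher. The hair keratin-associated genes KRTAP2-3 and KRTAP1-5 were 1.83-fold and 1.74-fold higher, although genes of this family are similar in sequence and signal shared between their probes was not excluded. Of the 9 detected KRTAP genes, 5 were negative and 4 positive (median -0.085, percentile 17.27). RNF144B, a ubiquitin ligase, was 1.75-fold higher. MRPS14, a mitochondrial ribosomal protein, was 1.72-fold higher, TMEM106B, a lysosomal membrane protein, 1.69-fold, and MTMR6, a phosphoinositide phosphatase, 1.68-fold. WDFY1 was 1.61-fold higher. NOG, the secreted BMP antagonist noggin, and ADGRG1, an adhesion G protein-coupled receptor, were each 1.60-fold higher. SNAR-C1, a small non-coding RNA of a family with near-identical copies, was 1.63-fold higher by the mean of its 5 probe sets. Its difference was 0.703 by that mean and 0.39 by the brightest of them. The control value of SNAR-C1 (7.45) lay just below the array median of 7.46.

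Among the lowest genes, EIF5A2, an isoform of a translation elongation factor, was 1.99-fold lower after centring (9.72 against 10.68 as deposited). GALNT3, which starts O-glycosylation like GALNT1, was also 1.99-fold lower, and RCBTB1 was 1.98-fold lower. ANKRD1, an ankyrin-repeat protein induced by YAP, and the interferon-inducible SAMD9 were each 1.97-fold lower. TDG, the thymine DNA glycosylase of base excision repair, was 1.91-fold lower. CLTRN (collectrin) was 1.86-fold lower, and KLHL15, an adaptor of cullin ubiquitin ligases, was 1.81-fold lower. FNIP2, a partner of folliculin, and RASA2, a GTPase-activating protein for Ras, were each 1.75-fold lower. KMO, an enzyme of kynurenine metabolism, POMK, a kinase that acts on O-mannose, and TMEM243 were each 1.72-fold lower. On the miR-95 array GALNT3 (6.97), KMO (6.82), FNIP2 (7.10), RASA2 (7.40) and ANKRD1 (7.48) read below that array's median of 7.495. These genes counted as detected only through the control array. Every one of the genes in these top and bottom groups kept its sign under each alternative tried. They were picked for large differences and most values moved little, so a change of sign was hardly possible.

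**Figure D2:**
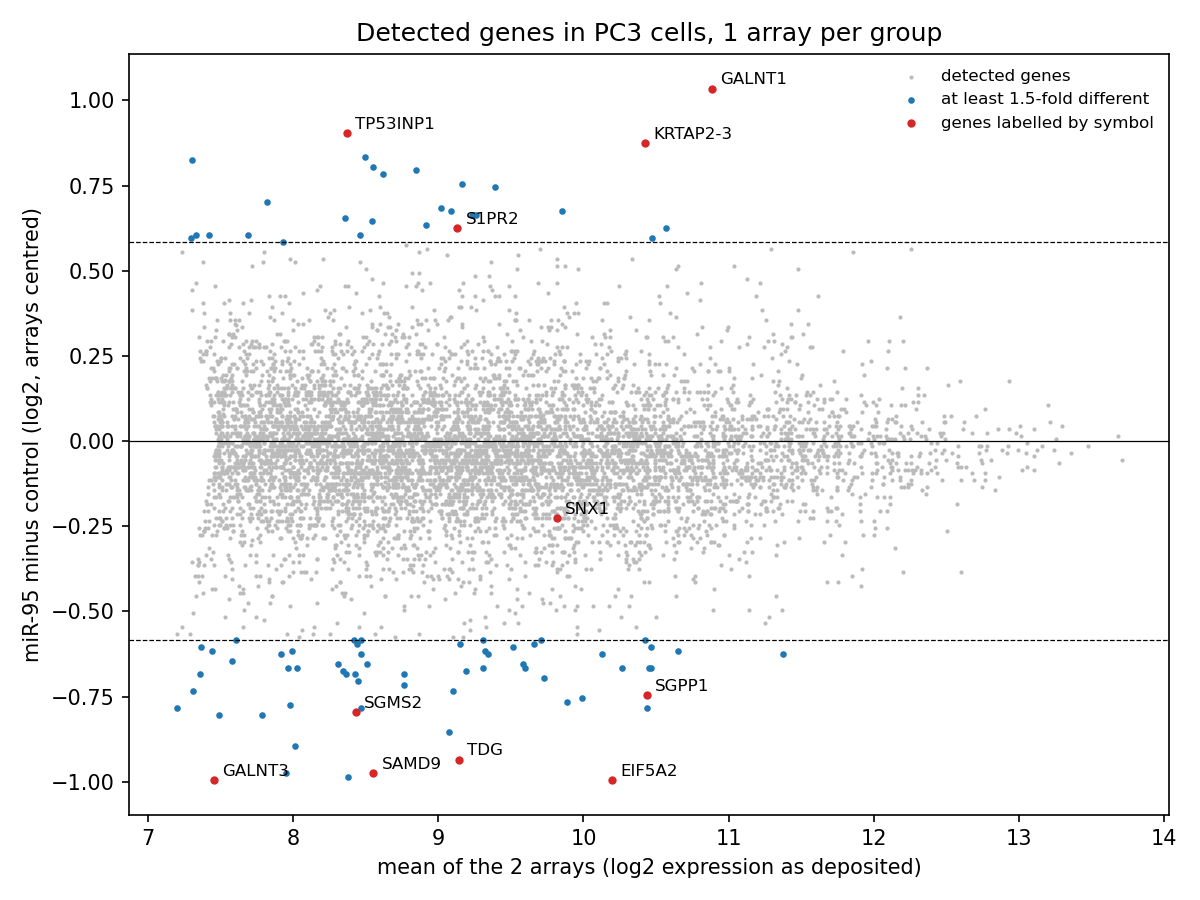
Difference between the arrays (vertical axis, miR-95 minus control, log2, arrays centred) against mean log2 expression (horizontal axis) for the 7081 detected genes, 1 point per gene. Dashed lines mark 1.5-fold, blue points lie past them and red points are labelled genes. GALNT1 is the 1 gene past 2-fold, and SGPP1 lies among the 61 genes at least 1.5-fold lower.

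Genes of DNA replication and the G1 to S transition were lower as a group on the miR-95 array. Of 32 detected members, 30 had negative and 2 positive differences, and the list median of -0.195 lay below all 10000 matched random lists. The differences were mostly small, and only 2 members were at least 1.5-fold lower. These were CCND1, the G1 cyclin D1, and GINS1, a subunit of the replicative helicase, each 1.54-fold lower. MCM10, a replication initiation factor, was 1.40-fold lower and CCNE1, cyclin E1, 1.32-fold lower. Against this, CCNA2, cyclin A2, was 1.38-fold higher and CDK6 1.12-fold higher. The list kept its place below the 2.5th percentile under each of the 12 alternatives tried, including random lists matched on gene span. Of these, the values as deposited shift every gene alike and could not change a percentile.

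The G2 and mitosis list lay lower by less, with 22 negative and 9 positive members of 31, a median of -0.105 and a percentile of 2.25. KIF4A, a chromosome kinesin, lay at the 1.5-fold limit (9.43 against 9.98 before centring), and MAD2L1, of the spindle checkpoint, was 1.28-fold lower. TOP2A, topoisomerase 2α, was 1.19-fold higher and NEK2, a centrosomal kinase, 1.16-fold higher. MKI67, the proliferation marker Ki-67, differed by -0.055. The list moved inside the central range in 3 of 12 alternatives, where its highest percentile was 3.23.

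Genes of DNA damage signalling were also lower. In the checkpoint list, 14 of 16 detected members had negative differences (median -0.145, percentile 0.80). WEE1, the kinase that restrains CDK1, was 1.52-fold lower and was the only member past 1.5-fold. Without it the list reached the 5.42th percentile, inside the central range. Leaving out a low member cannot lower the list median, and the random lists still held such genes. The phosphatase CDC25A was 1.45-fold lower and TIPIN, a replication fork protein, 1.38-fold lower, while the kinase ATR was 1.15-fold higher. In the double-strand break repair list, 17 of 19 detected members were negative (median -0.125, percentile 1.32) and 0 passed 1.5-fold. BRIP1, a helicase that binds BRCA1, was 1.35-fold lower and RAD54L, of homologous recombination, 1.31-fold lower. XRCC5, the Ku80 subunit of end joining, differed by 0.025. With random lists matched on gene span the repair list was at the 7.53th percentile, inside the central range, and the checkpoint list at 1.08. Among genes above the 75th percentile of expression both lay inside it, at 8.35 and 3.69.

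Of 24 p53 target genes, 13 were measured and 10 detected, and no probe set used here named CDKN1A. Of the detected members, 9 of 10 had positive differences (median 0.195, percentile 99.98), although PC3 cells lack functional p53. TP53INP1 was the only member past 1.5-fold. RRM2B, a ribonucleotide reductase subunit, was 1.25-fold higher, and TIGAR, a regulator of glycolysis, and SESN2, a stress-induced sestrin, were each 1.24-fold higher. AEN, the member with a negative difference, was at -0.025.

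Of 30 NF-kB targets and inflammatory cytokines, 19 were measured and 10 detected. No probe set used here named NFKBIA, TNFAIP3, IL6 or IL1B. The detected members were higher, with 9 of 10 positive (median 0.185, percentile 99.91). CXCL8, the neutrophil chemokine interleukin 8, and the cytokine IL24 were each 1.52-fold higher, both from control values below the array median (7.10 and 7.01). LIF, a cytokine of the interleukin 6 family, was 1.33-fold higher and the adhesion molecule ICAM1 1.22-fold higher. NFKB1 differed by -0.045. PTGS2, which encodes cyclooxygenase 2, lay below the detection rule on both arrays. It read 7.23 on the miR-95 array and 5.96 on the control array, and is named after its value was seen. The other members below the rule went both ways, from CCL2 at -0.255 to CXCL6 at 0.445.

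A further 4 lists lay above the central range, with 0 members past 1.5-fold in any of them. Of the ERBB and MAPK genes, 11 of 14 were positive (median 0.125, percentile 99.96). SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, was 1.27-fold higher and the receptor ERBB3 differed by 0.265 on the log2 scale, while the kinase MAP2K1 was 1.15-fold lower. Without the members shared with the immediate early genes, the percentile was 99.80. Of the immediate early genes, 13 of 17 were positive (median 0.095, percentile 99.84). IER2 was 1.22-fold higher and the phosphatase DUSP6 1.18-fold higher, while SRF, the serum response factor, was 1.30-fold lower. This list reached the 97.05th percentile, inside the central range, with the finer of 2 matchings on gene span.

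In the unfolded protein response list, 8 of 11 members were positive (median 0.125, percentile 99.80). The transcription factor XBP1 was 1.24-fold higher, the pseudokinase TRIB3 1.23-fold higher and SEL1L, of ER-associated degradation, 1.15-fold lower. In the list of Wnt targets and pathway members, 7 of 10 detected were positive (median 0.095, percentile 99.30). Most of these 10 are receptors, so the median says little about targets of the pathway. Members below the detection rule went both ways, from RNF43 at -0.715 to AXIN2 at 0.185. The receptors LRP6 and FZD8 were each 1.18-fold higher, LGR5 was 1.17-fold higher and FZD6 was 1.12-fold lower.

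Interferon-stimulated genes were lower on the miR-95 array. Of 18 detected members of the type I interferon list, 12 were negative and 6 positive (median -0.165, percentile 0.17), with 4 at least 1.5-fold lower and 0 higher. That sign share is near the 59.4% of all detected genes that were negative. The 4 were SAMD9 and its paralog SAMD9L (1.59-fold lower), and IFI44 and its paralog IFI44L (1.66-fold and 1.59-fold lower). DDX60, a helicase of antiviral RNA sensing, was 1.37-fold lower. IFITM3, a restriction factor of virus entry, and the transcription factor IRF7 were each 1.11-fold higher. Without SAMD9L and IFI44L the list median was -0.14 (percentile 0.75). Without all 4 it was -0.11 and lay inside the central range, at the 4.29th percentile. The direction of these shifts was fixed, since low members were left out of the list but not of the random lists.

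**Figure D3:**
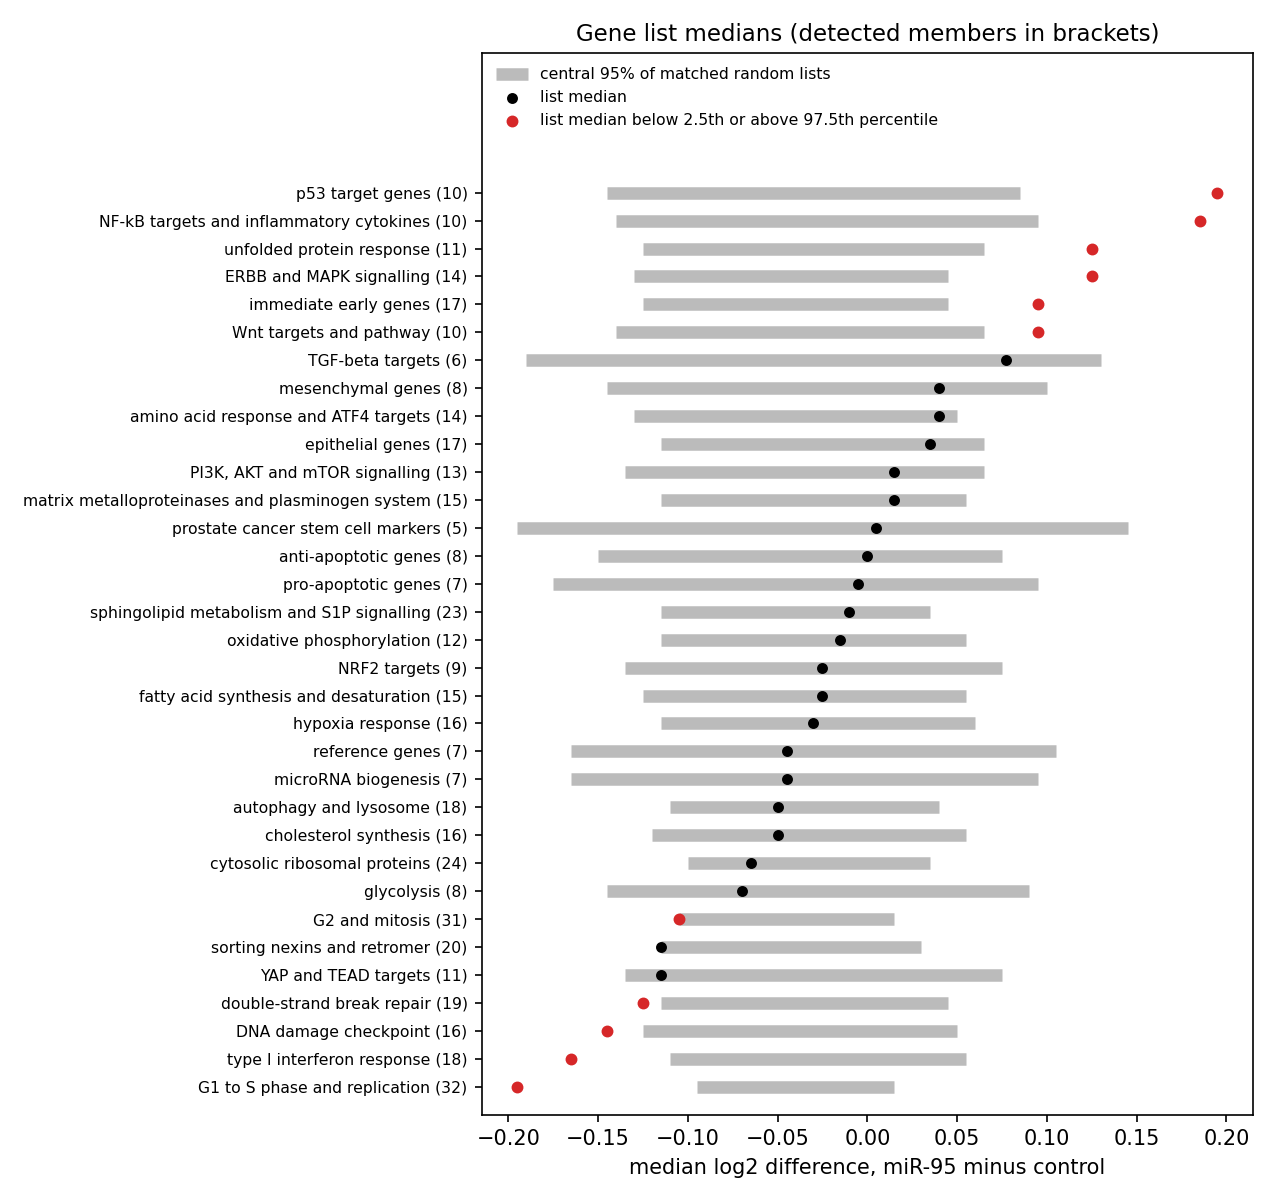
Median log2 difference (horizontal axis, miR-95 minus control) of the detected members of 33 gene lists, with the number of detected members in brackets. Grey bars give the central 95% of 10000 random lists matched on expression, and red points are the 5 lists below and the 6 above that range; the replication list lies lowest at -0.195 and the p53 target list highest at 0.195.

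The other 22 lists lay within the central range. The epithelial list had a median of 0.035 over 17 detected genes, but 0.155 among genes above the 75th percentile of expression, where it lay above the central range (percentile 99.33). The tight junction gene CLDN1 was 1.51-fold lower, CDS1, an enzyme of phospholipid synthesis, differed by -0.335, and CLDN3 was 1.19-fold higher. The mesenchymal list had a median of 0.04 over 8 genes. SNAI1, a repressor of epithelial genes, was 1.44-fold higher and the matrix cross-linking enzyme LOXL2 1.37-fold higher, while LOX was 1.19-fold lower. The control value of SNAI1 (7.10) lay below the array median. Apoptosis genes went both ways. BAK1, a pore-forming death effector, was 1.39-fold higher and PMAIP1 (NOXA) 1.40-fold lower. The survival gene BCL2A1 was 1.52-fold higher, from a control value below the array median (7.37). In the metalloproteinase and plasminogen list (median 0.015), ADAM9 was 1.24-fold higher and MMP1 1.21-fold higher, and ADAM17 was 1.40-fold lower. Sorting nexins and retromer genes had 17 of 20 members negative, with a median of -0.115 at the 2.67th percentile. This list lay below the 2.5th percentile after loess (1.79), among genes above the 75th percentile of expression (1.01) and with unmatched random lists (2.12), and at its edge without members past 1.5-fold. SNX1, at -0.225, lay close to SNX11 (-0.235) and SNX16 (-0.265). The YAP list (median -0.115) held ANKRD1 at 1.97-fold lower but lay at the 4.98th percentile. It lay below the central range with no filter on dim genes (1.65) and with detection at the 25th percentile (1.61). In the microRNA biogenesis list (median -0.045), TNRC6A, a scaffold of the silencing complex, was 1.40-fold higher.

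Lists of basic metabolism and housekeeping stayed near the median of all detected genes. Cytosolic ribosomal proteins had a median of -0.065, glycolysis -0.07, oxidative phosphorylation -0.015 and cholesterol synthesis -0.05. The 7 detected reference genes had a median of -0.045, with GAPDH at 0.015 and HPRT1 at -0.205. With random lists matched on gene span the ribosomal protein list lay at the 0.65th percentile, below the central range. The remaining lists also lay within the central range. Their medians were 0.077 for TGF-beta targets, 0.04 for amino acid response genes, 0.015 for PI3K and AKT signalling, 0.005 for stem cell markers, -0.025 for fatty acid synthesis, -0.025 for NRF2 targets, -0.03 for hypoxia and -0.05 for autophagy. Among their members, the phosphatase PHLPP2 of the PI3K and AKT list differed by -0.545, the thioredoxin reductase TXNRD1 of the NRF2 list by -0.535 and the surface marker CD44 of the stem cell list by -0.325. In the cholesterol list the lipid transfer gene STARD4 differed by 0.455.

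Markers of other cell types were mostly below the detection rule. The numbers detected were 2 of 13 measured fibroblast genes, 2 of 10 haematopoietic genes, 3 of 9 endothelial genes, 1 of 13 neuroendocrine genes, 2 of 10 basal genes and 4 of 10 luminal prostate genes. None of these detected markers was 1.5-fold different in either direction. Below the detection rule, the fibroblast marker LUM was 2.51-fold lower on the miR-95 array after centring (6.04 against 7.33 as deposited) and the neuroendocrine marker CHGB 1.52-fold lower (5.06 against 5.63 as deposited); both are named after their values were seen. Of the antigen presentation genes 2 were measured and detected, also with 0 past 1.5-fold, and of the cyclin-dependent kinase inhibitors 1 was measured, below the detection rule.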

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

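Chosen only after the differences had been seen were the tests on matching by gene span, the test of brightness without matching, the comparison of the cell cycle lists with each other, and the tests of dim probe sets.

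Probe sets without a gene name entered no comparison, yet 3871 of the 9553 were detected by the same rule. Of these, 16 were at least 1.5-fold higher and 31 at least 1.5-fold lower on the miR-95 array. Probe set 16978301 stands out because it is the 1 that lies more than 2-fold above the control array, at 10.60 against 9.42 as deposited, a difference of 1.145 after centring. That is larger than for any detected named gene. A further 5 were more than 2-fold lower, and the brightest of them, probe set 16809506, read 10.23 against 11.44 as deposited (2.37-fold lower after centring). No explanation was tested for these.

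The replication, mitosis, repair and checkpoint lists lay below matched random lists together. A trend with brightness is argued against, since after removal of a loess curve on mean expression 4 of the 4 lists stayed below the 2.5th percentile of random lists not matched on expression (highest 1.71; the 4 of 4 with matched lists decide nothing, as matching holds brightness already), and a trend with gene length is argued against as the whole cause, since 3 of the 4 stayed with either matching on gene span. For the double-strand break repair list it cannot be told apart, because its percentile moved from 1.32 to 7.53, neither past the limit nor near the middle. Among genes above the 75th percentile of expression, G1 to S stayed below the 2.5th percentile (0.0). The G2 and mitosis (2.85), checkpoint (3.69) and repair (8.35) lists lay inside the central range there, with medians of -0.105, -0.145 and -0.105. Noise of dim probe sets therefore stays open for these lists. A fall of both cell cycle lists alike, as fewer cycling cells might give, cannot be told apart either: the G1 to S median minus the G2 and mitosis median was -0.09, where reassignment of members gave -0.075 to 0.075 in the central 95%, but 1 array per group holds no variation between cultures and such a fall need not be equal in both lists. GC content was not tested, and an effect of miR-95, a difference in culture density and a difference between the 2 derived lines stay open, because 1 array per group does not separate them.

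The p53, NF-kB, immediate early, ERBB, unfolded protein and Wnt lists lay above matched random lists. A trend with gene length is argued against for most of them, since 6 of the 6 stayed above the central range with the coarser matching and 5 with the finer. For the immediate early genes, which reached 97.05 with the finer matching, it cannot be told apart. Noise of dim probe sets is argued against in the 4 lists that kept 5 members among genes above the 75th percentile of expression, where 4 of 4 stayed above (lowest percentile 97.93), and stays open for the p53 and NF-kB lists, which kept 2 and 3 members. Whether miR-95, culture conditions or the derivation of the lines is the cause was not separable in this design.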

How the results depend on the processing

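Matching on gene span and leaving out members past 1.5-fold were chosen only after the data were seen. Direction held for SGPP1 (-0.74 to -0.70) and SNX1 (-0.22 to -0.183) and for the 26 genes named by rank under the 5 alternatives that change values, where 127 values moved by less than the 0.126 spread and 3 by more (GALNT3 at -0.843 and KMO at -0.648 with the offset, SNAR-C1 at 0.39 with its brightest probe set). The counts followed the filter on dim genes by construction, since fewer or more genes were tested. Without a filter, 187 genes were at least 1.5-fold different (59 higher, 128 lower), with 7 at 2-fold higher and 4 at 2-fold lower. At the 25th percentile the 2-fold counts were 3 higher and 2 lower. At the 75th percentile 42 genes passed 1.5-fold (14 higher, 28 lower). The genes at least 1.5-fold lower numbered 45 with the values as deposited, 45 of them shared with the 61 of the main setting, and the 28 higher genes all remained among the 37. Lists below the 2.5th percentile numbered 5. Among genes above the 75th percentile, where 27 lists kept 5 members, they numbered 2, of which G1 to S was 1 of the original lists and sorting nexins was not. The type I interferon list kept fewer than 5 members there and got no percentile, so noise of dim probe sets stays open for it. When members past 1.5-fold were left out they numbered 3: G1 to S, double-strand break repair and sorting nexins, while checkpoint (5.42), G2 and mitosis (3.23) and interferon (4.29) moved inside. The repair and sorting nexin lists had 0 members past 1.5-fold. Their percentiles (1.35 and 2.5, against 1.32 and 2.67) therefore differed only by new random draws. Genes past 1.5-fold stayed in the random lists, and leaving out low members cannot lower a list median. The direction of the shifts of the checkpoint, G2 and mitosis and interferon lists was thus fixed. Of the 11 lists outside the central range, at least 10 stayed on their side under centring, offset, probe set choice, lower filters and unmatched lists; the cause of the losses was not tested. Under all alternatives together, 367 list medians moved by less than the SD of random lists and 25 by more, with no sign change among the 11. The unmatched lists and the matchings on gene span change only the random lists. List medians could not move there, nor in lists without members past 1.5-fold when such members were left out. These enter the 367 by construction. The values as deposited shift every gene alike, so no percentile could move under them. No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. The search for seed sites was not run. Dim probe sets limit the rest: of 6783 genes below the detection rule, 31 were at least 1.5-fold higher and 67 lower.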

Other observations

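The gene families in this part were picked only after their values had been seen, and so were the matching of families on gene span, the test of adjacent genes and the value of the same window after removal of the trend with gene length. Of 9 detected GALNT genes, which encode enzymes that start mucin-type O-glycosylation, 7 were negative and 2 positive (median -0.115, percentile 11.46). Only GALNT1 (2.05-fold higher) and GALNT3 (1.99-fold lower) passed 1.5-fold. Of all detected genes, 59.4% were negative. Among kinesins, 24 of 27 detected KIF genes were negative (median -0.145, percentile 0.18), and among centrosomal CEP genes 25 of 32 (median -0.135, percentile 0.05). Nucleoporins (NUP) were negative in 16 of 19 (percentile 1.29) and the ADAM proteases positive in 8 of 9 (percentile 99.46). Unlike these, the VPS genes belong to membrane trafficking, and they were negative in 20 of 32 (percentile 0.45). MCM genes, partly members of the replication list, were negative in 10 of 11 (percentile 0.83), and IFT genes positive in 7 of 10 (percentile 97.89). The G2 and mitosis list holds KIF genes and a CEP gene. ADAM genes are also in the metalloproteinase list, and VPS genes in the list of sorting nexins and retromer genes. These families are therefore not independent of those lists. KRTAP, given above, and SNAR, with 4 detected, were also looked at. With random lists matched on gene span as well, the percentiles were 1.3 for KIF, 2.02 for CEP and 99.57 for ADAM, while NUP lay inside the central range at 4.4. They were 0.75 for VPS, 0.86 for MCM and 99.3 for IFT.

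Differences of neighbouring genes were compared because the 2 stable lines may differ in the copy number of a chromosome segment. Genes were ordered along the chromosomes and differences limited to 0.5 either way. Adjacent detected genes correlated at r = 0.079 across genes, above the 0.023 that bounds the central 95% of 10000 shuffled orders. The most extreme mean over 25 neighbours, from ZNF846 to EPOR, was 0.163 relative to the median, just past the 0.158 of shuffled orders. Once the trend with gene length was removed, the same window had a mean of 0.138, and the most extreme window, from ZNF426 to TMEM205, had 0.14 against 0.156, so the call ended by a small margin and gene length and a copy number difference cannot be told apart for it. Adjacent genes still correlated at r = 0.044 after that step, above the 0.023 of shuffled orders, which argues against gene length as the whole source of that correlation; what else neighbours share was not tested.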
